A study of Homo sapiens with 18 samples.

How the data were processed

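RNA was measured by sequencing in MCF7, an established oestrogen-receptor-positive breast adenocarcinoma cell line. Per the labels, wild-type cells and HIF1α-mutant cells were grown in high-glucose medium with fetal calf serum at 21% oxygen, or moved to a hypoxic workstation at 1% oxygen for 3 h or 24 h. Each of the 6 groups has 3 libraries, 18 in all. Total RNA was purified with TRIzol and silica columns, and libraries were made with the KAPA Hyper Prep kit and sequenced on an Illumina instrument, per the labels' protocols. The labels do not say what the mutation is, whether the mutant cells are 1 clone, or whether the replicates are separate cultures. Genotype and cell line therefore change together, and each p-value sets a difference against the spread between these libraries.

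Each deposited table gives 1 value per Ensembl gene for 18988 genes, and the deposited values are a normalised read signal: gene counts divided by 1 size factor per library. Nothing in the tables names this unit, and it was read from the values. Within each library all values were whole multiples of 1 step, with a relative tolerance of 1e-06, so whole reads were recovered for 100% of values. The divisors matched the size factors that DESeq2 computes from the recovered reads, with a largest relative difference of 4.1e-15. The submitters' processing notes name TopHat2 2.1.1, DESeq2 1.16.1 and the GRCh37 genome build, without their roles. The counting tool, gene annotation and strand setting are not given in the notes used here. The tables hold a subset of genes, since the smallest total over the 18 libraries was 11 reads. Recovered depth ranged from 16597583 to 29995588 reads per library, and normalised totals from 22102324 to 23715631. At this depth a gene with few reads in a group carries a wide counting error, so ratios resting on 1 to 3 reads are given with an exact 95% interval. Such intervals cover counting error only. Ensembl identifiers were matched to symbols, and 592 had no match. Positions are on GRCh37.

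Genes with a normalised value of at least 10 in at least 3 libraries were kept, 16268 in all. They were tested with limma 3.58.1 in R 4.3.3 on log2(value + 2), with a mean for each of the 6 groups, a mean-variance trend and 1 estimate of spread from all 18 libraries. A fold change is on this log2(value + 2) scale and understates the change of low genes. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The planned design assumed raw counts and edgeR. It was kept as written, but because the tables hold normalised values the main test is limma, and edgeR 4.0.16 on the recovered reads is an alternative added after the data were seen.

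The 11 comparisons were hypoxia against normoxia in each genotype at 3 h and at 24 h, the difference between those responses at each time (the interaction, mutant response minus wild-type response), mutant against wild type in each oxygen condition, and 24 h against 3 h in each genotype. A wild-type response was counted as attenuated when the gene was called in the wild type and its interaction was called with the opposite sign. The comparisons, gene lists, rule for named genes and most of the other settings listed below were chosen before the data were examined.

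The 24 gene lists, with 459 members of which 415 were tested, were glycolysis, oxygen sensing, other HIF targets, collagen modification, oxygen-dependent chromatin dioxygenases, the integrated stress and unfolded protein responses, oestrogen response, cell cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, sterol and lipid synthesis, interferon-stimulated genes, immediate early genes, p53 targets, oxidative and metal stress, ribosome biogenesis, ribosomal proteins, luminal epithelium, mesenchymal transition, basal epithelium, fibroblast, leukocyte, replication-dependent histones and abundant nuclear RNAs. Basal, fibroblast and leukocyte genes mark other cell types, and histone and nuclear RNA genes are possible signs of RNA selection and quality. Whether changes in histone and nuclear RNA genes came from RNA quality or from the cells was not tested. Each list was tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over 264 tests, and again with an estimated correlation. Calls are given over all genes tested, and adjusted over the list alone. Where a list member had 3 reads or fewer in 1 group of a pairwise comparison, the list median was recomputed from read ratios, with a group at 0 put at 3 reads over the group. This arose in 7 of 216 tests, for 1 member of 35 or 2 of 21, and moved no median. A median responds little to so few members, so this does not check the list tests.

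Genes are named by a fixed rule. HIF1A, EPAS1, ARNT and a panel of HIF targets (EGLN3, CA9, VEGFA, PDK1, PGK1, LDHA, SLC2A1, BNIP3, NDRG1, ANKRD37, KDM3A, ADM, DDIT4 and P4HA1) may be named in each comparison. So may up to 6 genes with the largest rise and 6 with the largest fall among called genes, with a mean log2 CPM of at least 1 and, outside the interactions, no overlap between libraries. Up to 4 members of each list with the smallest p complete the rule. One long non-coding RNA that met the rule is reported neither here nor in the result tables. Other genes that met the rule are in the result tables, and only some of them are named in the text.

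Alternatives were other scalings (upper quartile, library size only, TMM), no filter, a filter of 5 CPM in 3 libraries, a DESeq2 1.42.0 Wald test on the recovered reads, fits of only the groups compared, the replicate number as a term, a 2-fold minimum change, and leaving out each library. Pseudocounts of 0.5 and 8, TMM and edgeR were added after the data were seen. A setting with DESeq2 size factors, chosen before the data were seen, is the deposited scaling itself.

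The tests were run on simulated data with known changes. The changed genes, 50 for each size of change, came only from genes with a mean of at least 50 normalised reads. Recovery of lower genes was therefore not measured. Reads were drawn separately for each gene, without shifts shared across a library. In simulated wild-type libraries at 3 h, over 16268 genes, 64% of genes changed 1.25-fold and 98% of genes changed 2-fold were recovered with the right sign. For the interaction at 3 h these shares were 30% and 96%, and for the interaction at 24 h 36% and 88%. Where the response was simulated equal in both genotypes, 4 of 3935 genes were counted as attenuated at 3 h and 7 of 10261 at 24 h.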

Results

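Gene expression was profiled in 18 libraries of MCF7 breast cancer cells, 3 for each combination of 2 genotypes and 3 oxygen conditions. The design addresses how HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, contributes to the transcriptional response to low oxygen. The first 2 principal components of the log values held 42.5% and 24.6% of the variance. The first separated the 9 mutant from the 9 wild-type libraries, and the second separated the 24 h libraries from the others. Transcripts of the 17 mitochondrially encoded genes took 7.73% to 11.98% of reads per library. Among mutant libraries, normoxia replicate 3 was at 11.8%, against 9.62% and 9.68% in its partners, and 3 h replicate 2 at 10.1%, against 8.21% and 8.60%. The mutant 24 h libraries were at 9.38%, 8.68% and 7.73%. Replicate pairs differed by more than read sampling gives, with a chi-square per gene of 1.61 to 11.4, the highest between mutant 24 h replicates 1 and 3.

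HIF1A (ENSG00000100644, chromosome 14, 62162231 to 62214977) was still transcribed in mutant cells. Its normalised read counts in wild-type cells were 8140, 8316 and 8021 in normoxia, 7914, 7582 and 7625 at 3 h, and 5999, 5619 and 5806 at 24 h. In mutant cells they were 5993, 5943 and 6868 in normoxia, 6001, 6358 and 6336 at 3 h, and 8001, 8344 and 8116 at 24 h. A gene total does not show which exons the reads came from, so these values neither check nor locate the mutation. The related subunit EPAS1 (ENSG00000116016, chromosome 2, 46520806 to 46613836) had 237 ± 6.04 normalised reads (SD, n = 3) in wild-type normoxia and 421 ± 41.6 in mutant normoxia. At 3 h it had 243 ± 19.7 in wild-type and 340 ± 5.81 in mutant cells. It reached 313 ± 11.6 in wild-type and 774 ± 46.4 in mutant cells at 24 h. CA9 (ENSG00000107159, chromosome 9, 35673925 to 35681156), a carbonic anhydrase used as a hypoxia marker, had 3 reads over the wild-type normoxia libraries, 96 at 3 h and 3196 at 24 h. Its ratio to normoxia was 31.5 at 3 h (exact 95% counting interval 10.4 to 155) and 1308 at 24 h (447 to 6344). In mutant cells CA9 had 2 reads in normoxia, 3 at 3 h and 3 at 24 h, and the ratios were 1.26 (0.144 to 15.04) and 1.21 (0.139 to 14.5).

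**Figure D1:**
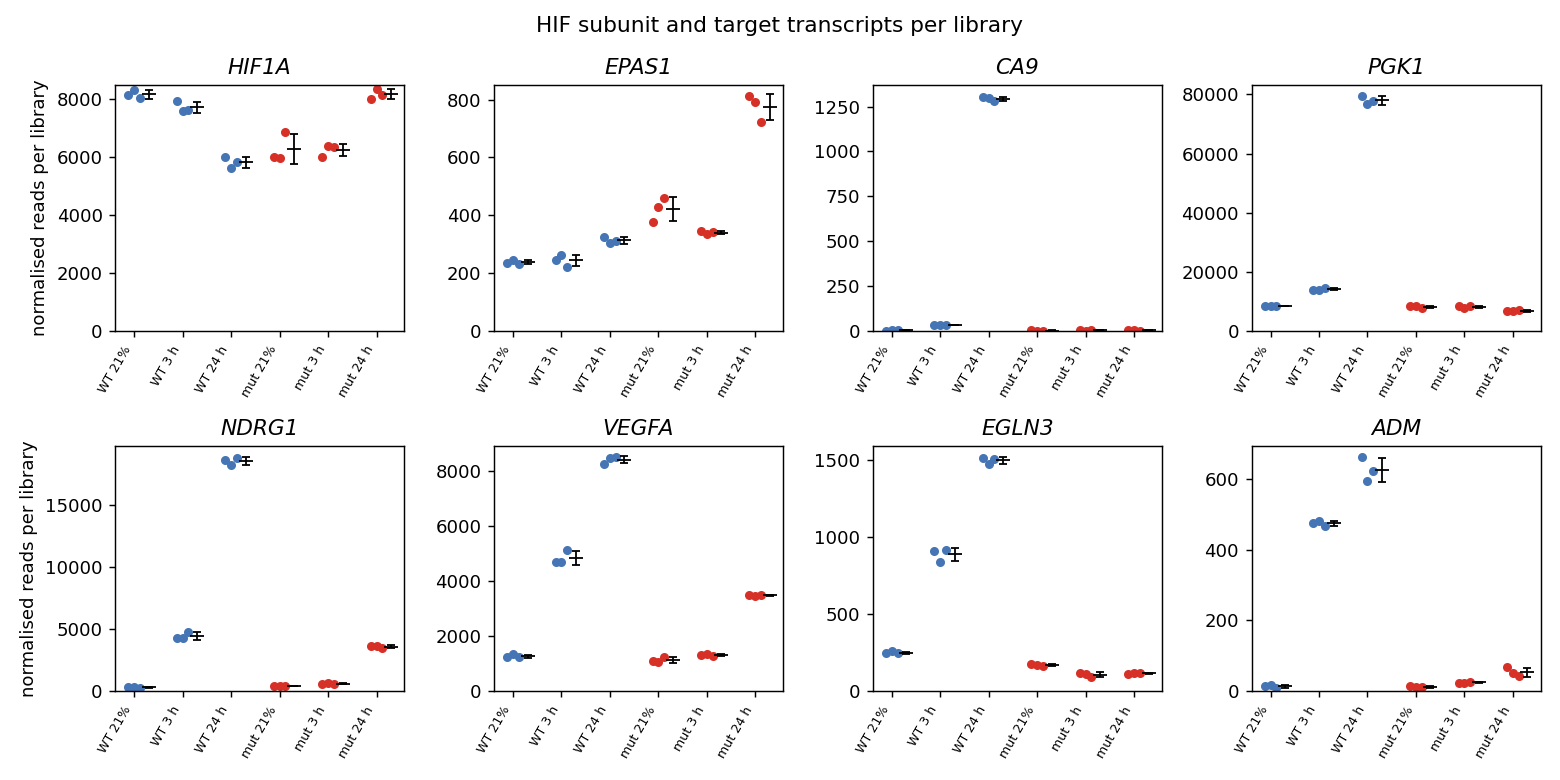
Normalised reads per library for HIF1A, EPAS1 and 6 HIF targets in the 6 groups, with a point for each library and a bar for the mean and SD of 3 libraries. PGK1 averages 77980 in wild-type and 6667 in mutant cells at 24 h, while EPAS1 is highest in mutant cells at 24 h, at 774.

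Within 3 h of hypoxia, wild-type cells raised a broad set of HIF targets. NDRG1 (ENSG00000104419, chromosome 8, 134249418 to 134314265), a stress-responsive differentiation gene, went from 343 ± 37.5 to 4448 ± 312 normalised reads (SD, n = 3), a log2 change of 3.69 ± 0.063 (SE, adjusted p = 5.28e-27). ADM, which encodes the vasodilator adrenomedullin, rose by 4.94 ± 0.181, and the angiogenic factor VEGFA rose by 1.92 ± 0.051. DDIT4, an inhibitor of mTOR signalling, rose by 3.27. The largest rise was that of CYP1A1 (ENSG00000140465, chromosome 15, 75011883 to 75017877), a monooxygenase induced through the aryl hydrocarbon receptor, from 182 ± 19.9 to 20790 ± 1160.

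Of 35 other HIF targets, 31 rose and 4 were not called at 3 h (32 rose and 1 fell, adjusted over the list alone), with a median log2 change of 1.46 (adjusted p = 1.22e-62, and 8.09e-07 with an estimated correlation). Members included BHLHE40 at 2.79 and STC2 at 1.68. Of 23 glycolysis genes, 21 rose (21, adjusted over the list alone). The regulators of fructose 2,6-bisphosphate PFKFB4 and PFKFB3 rose by 3.40 and 2.46, and PDK1, which restrains pyruvate entry into mitochondria, by 2.68. The glycolysis median was 0.54 (adjusted p = 3.43e-37). Collagen-modifying enzymes rose in 6 of 10 cases (8, adjusted over the list alone), among them P4HA1 at 1.28 and LOXL2 at 1.30 (adjusted p = 3.53e-07). Of 20 oxygen-dependent chromatin dioxygenases, 13 rose and 1 fell, the same counts adjusted over the list alone. KDM3A led with 2.14, and the median was 0.17 (adjusted p = 7.24e-07). Among 12 oxygen-sensing genes, EGLN3, EGLN1 and CITED2 rose, by 1.81, 1.40 and 1.04. The list median was -0.05, its mean was 0.31 and the test pointed up (adjusted p = 0.101). HIF1A itself did not pass, at -0.08 (adjusted p = 0.232). It passed with library size only (adjusted p = 0.0472), while the other settings gave 0.0800 to 0.433.

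Immediate early genes rose in 10 of 15 cases and fell in 1 (11 and 1, adjusted over the list alone), with FOS at 2.37, JUN at 1.38 and EGR3 at -1.12 (adjusted p = 9.73e-13). Oestrogen response genes fell in 16 of 24 cases and rose in 2 (16 and 3, adjusted over the list alone). The progesterone receptor gene PGR fell by 0.99, the chemokine gene CXCL12 by 0.99 and the potassium channel gene KCNK5 by 1.35 (list adjusted p = 2.61e-10). Cell cycle genes fell in 12 of 32 cases (14, adjusted over the list alone), with CDC6 at -0.43 and CCNE1 at -0.63. That test gave adjusted p = 8.17e-05, and adjusted p = 0.103 with an estimated correlation. Oxidative and metal stress genes rose in 5 of 12 cases (5, adjusted over the list alone), led by the cystine transporter gene SLC7A11 at 1.61 (adjusted p = 3.08e-04, and adjusted p = 0.0570 with an estimated correlation). Of 9 histone genes 2 rose, and of 7 nuclear RNA genes 1 rose and 2 fell. Their tests gave adjusted p = 0.474 and 0.640. In all, 2963 of 16268 genes (18.2%) were called, 1713 higher and 1250 lower, and 288 rose and 56 fell at least 2-fold. The higher share was 57.8%, against 45.9% with upper-quartile scaling and 47.7% with library size only.

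After 24 h the wild-type response was larger and wider. The glycolytic kinase gene PGK1 (ENSG00000102144, chromosome X, 77166236 to 77384792) went from 8352 ± 166 to 77980 ± 1498 normalised reads (SD, n = 3), a log2 change of 3.22 ± 0.040. NDRG1 reached 18580 ± 292, a rise of 5.76 ± 0.063. The synaptic scaffold gene PPFIA4 rose by 5.89, the aldolase gene ALDOC by 5.18 and the ubiquitin ligase gene RNF183 by 5.02. RET, a receptor tyrosine kinase gene, fell by 2.22 and the transglutaminase gene TGM2 fell by 2.30. HIF1A fell by 0.49 ± 0.045 and EPAS1 rose by 0.40.

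At this time 22 of 23 glycolysis genes rose, with a median of 2.07 (adjusted p = 2.96e-23, and 9.70e-04 with an estimated correlation). Of 35 other HIF targets, 33 rose and 2 fell, and the mitophagy genes BNIP3 and BNIP3L rose by 3.93 and 3.36 (median 2.72, adjusted p = 1.02e-25). Collagen-modifying enzymes rose in 7 of 10 cases and fell in 2, with LOXL2 at 4.24 and P4HA2 at 2.65 (adjusted p = 9.75e-05). Counts for these 3 lists were the same adjusted over the list alone. Of 32 cell cycle genes, 29 fell (29, adjusted over the list alone), including the replication genes PCNA, at -1.32, and MCM6, at -1.25 (median -0.89, adjusted p = 1.83e-14, and 0.00659 with an estimated correlation). Ribosome biogenesis genes fell in 16 of 20 cases and rose in 1, as they did adjusted over the list alone, with NOP56 at -1.14 and NOLC1 at -1.08 (adjusted p = 6.64e-09). Ribosomal protein genes moved the other way, with 22 of 26 higher (22, adjusted over the list alone) by a median of 0.25. The ribosomal protein test gave adjusted p = 1.74e-05, and adjusted p = 0.161 with an estimated correlation.

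Mitochondrially encoded genes fell in 11 of 13 cases (12, adjusted over the list alone), with MT-ND2 at -1.28 (adjusted p = 6.72e-04, and adjusted p = 0.541 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 19 of 33 cases and rose in 5, the same adjusted over the list alone (adjusted p = 0.0138, and adjusted p = 0.488 with an estimated correlation). Oestrogen response genes fell in 15 of 24 cases and rose in 5, with the cyclin gene CCND1 among those that rose, at 0.62 (adjusted p = 0.00147, and adjusted p = 0.0776 with an estimated correlation). Of 19 p53 targets, 12 rose and 4 fell, with the stress cytokine gene GDF15 at 1.89 (adjusted p = 0.00188, and adjusted p = 0.261 with an estimated correlation). Luminal epithelial genes rose in 11 of 17 cases and fell in 3, among them KRT19 at 1.22 (adjusted p = 0.0125, and adjusted p = 0.461 with an estimated correlation). Counts for these last 3 lists did not change when adjusted over the list alone. The mesenchymal list gave adjusted p = 0.0568 with ITGA5 at 1.90, and the basal list 0.0532 with EGFR at 1.98. Fibroblast and leukocyte genes, of which 4 and 2 were tested, gave adjusted p = 0.474 and 0.760. Nuclear RNA genes rose in 4 of 7 cases, with MALAT1 at 1.43 and NEAT1 at 1.62 (adjusted p = 0.0135, and adjusted p = 0.223 with an estimated correlation). Calls numbered 9947 (61.1%), 4917 higher and 5030 lower, and 1130 rose and 599 fell at least 2-fold.

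The direct test of 24 h against 3 h in wild-type cells called 9079 genes, 4468 higher and 4611 lower. PGK1 rose further by 2.47 ± 0.040 (SE, n = 3 per group), NDRG1 by 2.06 and ALDOC by 3.50, while ANKRD37 was at 0.21 (adjusted p = 0.609). CYP1A1 fell by 2.17 and the transcription factor gene ETV5 by 2.43. Between these times 21 of 23 glycolysis genes rose (21, adjusted over the list alone, test adjusted p = 3.17e-19). Over the same interval 25 of 32 cell cycle genes fell (26, adjusted over the list alone), with PCNA at -1.18 (adjusted p = 4.57e-14). Ribosome biogenesis genes fell in 17 of 20 cases (17, adjusted over the list alone, test adjusted p = 1.04e-09). Nuclear RNAs, a possible sign of RNA selection and quality, rose in 5 of 7 cases (5, adjusted over the list alone). MALAT1 was at 1.41, NEAT1 at 1.23 and KCNQ1OT1 at 1.14 (list adjusted p = 0.00224, and adjusted p = 0.131 with an estimated correlation).

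In mutant cells the panel HIF targets went different ways in the first 3 h. PGK1 was at 0.00 ± 0.040 (SE, n = 3 per group, adjusted p = 0.980) and LDHA, which encodes lactate dehydrogenase A, at -0.04 (adjusted p = 0.507). EGLN3 fell by 0.65 and the glucose transporter gene SLC2A1 by 0.25. EPAS1 fell by 0.30 ± 0.079 (adjusted p = 0.00662), a call lost without mutant normoxia replicate 3 (adjusted p = 0.0581), within a range of 0.00197 to 0.0581 over its alternatives. NDRG1 rose by 0.45 ± 0.063, KDM3A by 0.51, ADM by 0.88 and DDIT4 by 1.21. The ankyrin repeat gene ANKRD37 rose by 1.26 ± 0.325 (adjusted p = 0.00594), a call lost with only the groups compared (adjusted p = 0.106) and without mutant normoxia replicate 1 (adjusted p = 0.0794), within a range of 1.06e-04 to 0.106 over its alternatives. The largest rises were CYP1A1, from 139 ± 31.2 to 26040 ± 2709 normalised reads (SD, n = 3), RASD1 at 4.10, CYP1B1 at 3.90 and TIPARP at 2.97.

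The oestrogen response list fell in 18 of 24 cases and rose in 2 (19 and 2, adjusted over the list alone), with PGR at -0.93 and MYB at -0.60 (adjusted p = 1.19e-16, and 5.58e-04 with an estimated correlation). Of 35 other HIF targets, 12 rose and 5 fell (13 and 6, adjusted over the list alone), with STC2 at 0.92 and the glycogen regulator gene PPP1R3C at -1.70. Their median was 0.15 (adjusted p = 0.00497, and adjusted p = 0.0915 with an estimated correlation). Glycolysis gave adjusted p = 0.344, with a median of -0.02, and PFKFB3 fell by 0.90. Immediate early genes rose in 8 of 15 cases and fell in 3, as they did adjusted over the list alone, with JUN at 1.78 and DUSP1 at 1.46 (adjusted p = 5.11e-04, and adjusted p = 0.0886 with an estimated correlation). Cell cycle genes fell in 14 of 32 cases (17, adjusted over the list alone), among them CDC6 at -0.37 (adjusted p = 2.17e-06, and adjusted p = 0.0570 with an estimated correlation). The histone list rose in 5 of 9 cases (6 rose and 1 fell, adjusted over the list alone), with H2BC21 at 0.46 (adjusted p = 0.00343, and 0.0343 with an estimated correlation). NEAT1 rose by 1.21 among nuclear RNAs, of which 4 of 7 rose (4, adjusted over the list alone, test adjusted p = 0.00179, and adjusted p = 0.123 with an estimated correlation). Mitochondrially encoded genes fell in 5 of 13 cases (5, adjusted over the list alone), with MT-ND1 at -1.25 and MT-ND2 at -0.91 (adjusted p = 4.57e-05, and adjusted p = 0.422 with an estimated correlation). In total 2823 genes (17.4%) were called, 1550 higher and 1273 lower. The higher share was 54.9%, against 45.4% with upper-quartile scaling.

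At 24 h mutant cells had a large response, partly shared with wild-type cells. Of its 4768 rises and 4538 falls, 2759 and 2736 were called in the same direction in wild-type cells. NDRG1 reached 3598 ± 112 normalised reads (SD, n = 3) from 443 ± 23.2, a log2 rise of 3.02 ± 0.063, and VEGFA rose by 1.61 ± 0.051. PGK1 fell by 0.29 and P4HA1 was at -0.01 (adjusted p = 0.902). The stress-induced chromatin gene NUPR1 rose by 5.25, the basal keratin gene KRT17 by 4.20, LOXL2 by 3.93 and the stress transcription factor gene ATF3 by 3.37. In wild-type cells the means of KRT17, LOXL2 and ATF3 also went up, from 27.8, 230 and 32.7 to 223.5, 4367 and 124.5 normalised reads. HIF1A rose by 0.38 ± 0.045 in mutant cells and EPAS1 by 0.88 ± 0.079, while the adenosine receptor gene ADORA1 fell by 2.92.

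Sterol and lipid synthesis genes rose in 20 of 22 cases and fell in 2, the same adjusted over the list alone. SCD, which desaturates fatty acids, rose by 1.19 and MVD by 1.23 (list median 0.75, adjusted p = 1.46e-11, and 0.0343 with an estimated correlation). SCD also went up in wild-type cells, from 32520 ± 904 to 111500 ± 4211 normalised reads (SD, n = 3). The integrated stress and unfolded protein responses rose in 16 of 23 cases and fell in 5, with ATF4 at 1.06 and the asparagine synthetase gene ASNS at 1.75 (adjusted p = 9.75e-05, and adjusted p = 0.143 with an estimated correlation). Oxidative and metal stress genes rose in 8 of 12 cases, with SLC7A11 at 3.10 and HMOX1 at 2.17 (adjusted p = 9.75e-05, and 0.0426 with an estimated correlation). Cell cycle genes fell in 22 of 32 cases and rose in 7, with CCNE2 at -2.14 (adjusted p = 1.87e-09, and 0.0221 with an estimated correlation). Counts for these 3 lists did not change when adjusted over the list alone. Of 35 other HIF targets, 22 rose and 7 fell (23 and 7, adjusted over the list alone, median 0.47, adjusted p = 6.86e-04, and 0.0438 with an estimated correlation). Glycolysis genes rose in 11 cases and fell in 5 (11 and 5, adjusted over the list alone, test adjusted p = 0.128). Oestrogen response genes fell in 17 of 24 cases and rose in 5, as they did adjusted over the list alone, with the receptor gene ESR1 at -0.73 (adjusted p = 1.23e-04, and 0.0381 with an estimated correlation). Of 9 histone genes, 5 fell (5, adjusted over the list alone, adjusted p = 0.0406, and adjusted p = 0.111 with an estimated correlation). Nuclear RNAs rose in 5 of 7 cases (5, adjusted over the list alone, adjusted p = 0.00107, and adjusted p = 0.108 with an estimated correlation). Calls numbered 9306 (57.2%), 4768 higher and 4538 lower. The higher share was 51.2%, against 41.1% with library size only.

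Between 3 h and 24 h, mutant cells raised NUPR1 by 4.17 ± 0.227 (SE, n = 3 per group), LOXL2 by 3.38 and NDRG1 by 2.57. KLHL4 fell by 2.23. Sterol and lipid synthesis genes rose in 20 of 22 cases and fell in 2 (20 and 2, adjusted over the list alone), with LDLR at 1.07 (adjusted p = 7.49e-14, and 0.0221 with an estimated correlation). Interferon-stimulated genes rose in 16 of 21 cases (16, adjusted over the list alone), with ISG15 at 0.87 (adjusted p = 8.67e-05, and adjusted p = 0.329 with an estimated correlation). Histone genes fell in 7 of 9 cases (7, adjusted over the list alone, adjusted p = 8.50e-05, and 0.00770 with an estimated correlation). Nuclear RNAs rose in 5 of 7 cases and fell in 1 (5 and 1, adjusted over the list alone), with MALAT1 at 1.03 and NEAT1 at 0.83 (adjusted p = 0.0101, and adjusted p = 0.201 with an estimated correlation). This test called 8347 genes, 4318 higher and 4029 lower. The higher share was 51.7%, against 40.2% with library size only.

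The interaction at 3 h asks which hypoxia responses differed between genotypes. HIF targets responded less in mutant cells: the difference was -3.24 ± 0.089 for NDRG1 (SE, n = 3 per group, adjusted p = 2.52e-21), -2.80 for PDK1, -1.73 for VEGFA and -0.76 for PGK1. ADM differed by -4.06 ± 0.257 and PPFIA4 by -4.20. FOS (ENSG00000170345, chromosome 14, 75745529 to 75748933) differed by -3.60 ± 0.120. The long non-coding host gene of miR-210, MIR210HG, differed by -3.55.

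Responses were lower in the mutant for 30 of 35 other HIF targets (32 lower and 1 higher, adjusted over the list alone, median -1.45, adjusted p = 2.46e-100, and 1.03e-07 with an estimated correlation) and for 17 of 23 glycolysis genes (21, adjusted over the list alone, median -0.55, adjusted p = 2.67e-62, and 1.79e-05 with an estimated correlation). The same held for 6 of 10 collagen-modifying enzymes (7, adjusted over the list alone, median -0.59, adjusted p = 2.06e-11), and for EGLN3, EGLN1 and CITED2 among 12 oxygen-sensing genes (5, adjusted over the list alone, median -0.07, adjusted p = 6.05e-07, and 0.0163 with an estimated correlation). Among chromatin dioxygenases 6 of 20 responded less (7 less and 1 more, adjusted over the list alone), with KDM3A at -1.63 (adjusted p = 3.08e-04, and adjusted p = 0.0615 with an estimated correlation). Immediate early genes went both ways, 6 lower and 3 higher (8 and 3, adjusted over the list alone), with JUNB at -0.76 and JUN at 0.41 (adjusted p = 9.54e-05, and adjusted p = 0.0570 with an estimated correlation). The oestrogen response, cell cycle and p53 lists gave adjusted p = 0.114, 0.711 and 0.638, which does not show equal responses. Histone genes responded more in mutant cells in 3 of 9 cases (3, adjusted over the list alone, median 0.15, adjusted p = 0.00712, and 0.0464 with an estimated correlation), and nuclear RNAs in 3 of 7 cases (5, adjusted over the list alone, median 0.44, adjusted p = 3.26e-06, and 0.0311 with an estimated correlation). In all, 630 genes (3.87%) were called, 167 with a higher and 463 with a lower response in the mutant. For CA9, with few reads in 3 of the 4 groups, the call was lost in the count models (-4.65, adjusted p = 0.0626 in DESeq2, and -4.53, adjusted p = 0.162 in edgeR, against -3.37 in limma), within a range of 5.47e-07 to 0.162 over its alternatives.

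By 24 h the genotypes differed in their response at 7319 genes (45.0%), 3974 with a higher and 3345 with a lower response in the mutant. PGK1 differed by -3.51 ± 0.057 (SE, n = 3 per group, adjusted p = 4.87e-27), BNIP3 by -3.67, LDHA by -2.78 and PPFIA4 by -6.36. NDRG1 differed by -2.74 and VEGFA by -1.11, both having risen in each genotype. NUPR1 differed by 3.67, the matrix-associated growth regulator gene CCN2 by 3.16 ± 0.324 and the coactivator gene PPARGC1B by 2.46 ± 0.108. HIF1A differed by 0.87 ± 0.063 and EPAS1 by 0.48 ± 0.112.

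The mutant response was lower for 21 of 23 glycolysis genes and higher for 1 (21 and 1, adjusted over the list alone, median -1.76, adjusted p = 9.74e-30), and lower for 32 of 35 other HIF targets and higher for 1 (32 and 1, adjusted over the list alone, median -2.13, adjusted p = 4.25e-32). Collagen-modifying enzymes responded less in 6 of 10 cases and more in 1 (7 and 1, adjusted over the list alone, median -1.23, adjusted p = 7.42e-06, and 0.00978 with an estimated correlation), with PLOD2 at -2.48. Chromatin dioxygenases responded less in 13 of 20 cases and more in 4 (13 and 4, adjusted over the list alone, median -0.34, adjusted p = 7.72e-05, and 0.0426 with an estimated correlation). Ribosome biogenesis genes, lower in wild-type cells, responded higher in the mutant in 17 of 20 cases and lower in 2 (17 and 2, adjusted over the list alone, median 0.70, adjusted p = 6.59e-09, and 0.00446 with an estimated correlation), with NOP2 at 1.26. Sterol and lipid synthesis genes responded more in 19 of 22 cases and less in 1 (19 and 1, adjusted over the list alone), with HMGCS1 at 1.36 (adjusted p = 1.54e-08, and adjusted p = 0.0662 with an estimated correlation). The stress response list responded more in 17 of 23 cases and less in 2 (17 and 2, adjusted over the list alone), with ASNS at 1.75 and DDIT3 at 1.62 (adjusted p = 6.79e-05, and adjusted p = 0.133 with an estimated correlation). Oxidative phosphorylation genes did so in 18 of 33 cases and the reverse in 1 (19 and 1, adjusted over the list alone, adjusted p = 3.84e-04, and adjusted p = 0.275 with an estimated correlation). Histone genes responded less in 7 of 9 cases and more in 1 (7 and 1, adjusted over the list alone, median -0.50, adjusted p = 6.28e-04, and 0.0168 with an estimated correlation), with H4C8 at -1.33. The higher share of calls was 54.3%, against 41.6% with upper-quartile scaling.

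**Figure D2:**
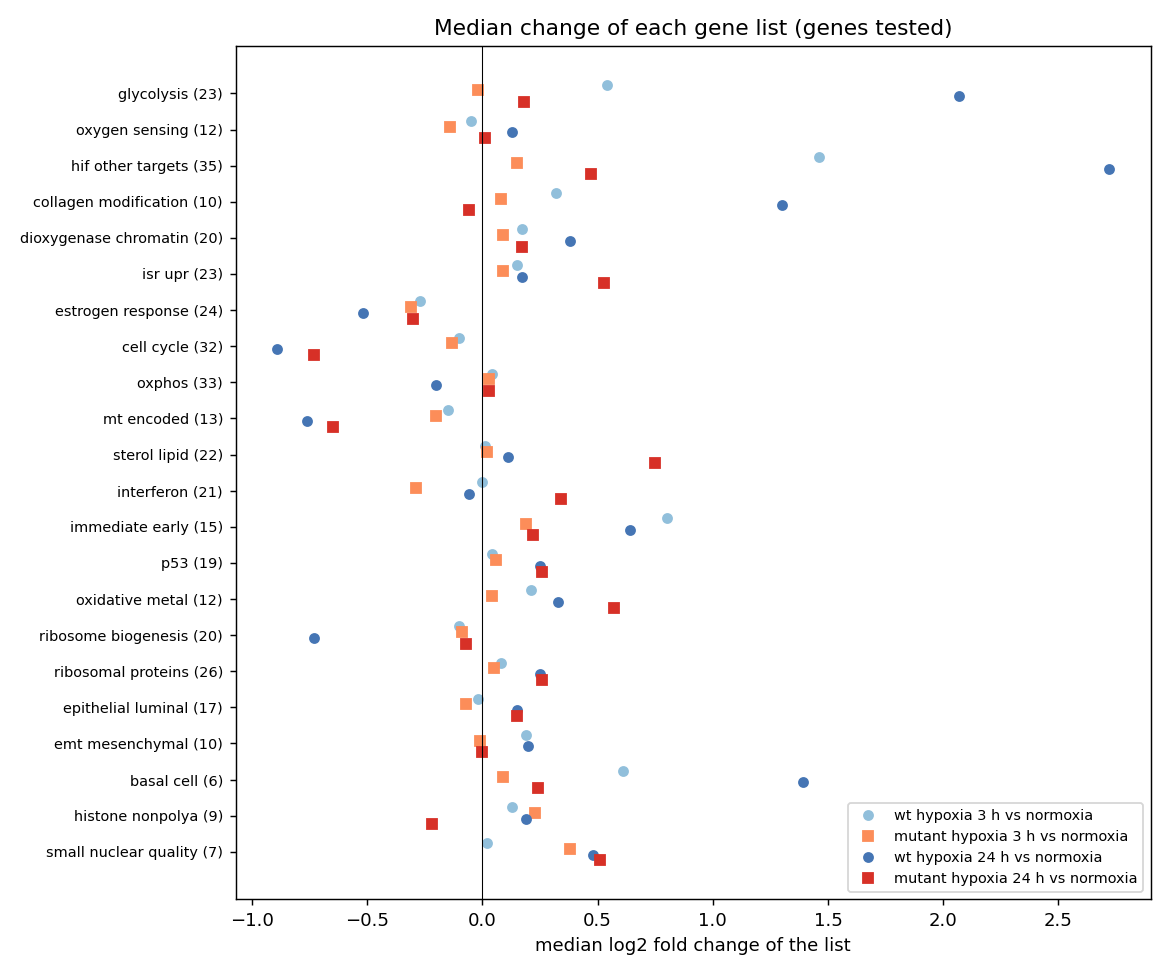
Median log2 change of 22 gene lists in hypoxia against normoxia, as circles for wild-type and squares for mutant cells, with the number of genes tested in brackets. Other HIF targets lie at 2.72 in wild-type and 0.47 in mutant cells at 24 h, while the cell cycle list lies at -0.89 and -0.73.

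Part of the wild-type response was attenuated in mutant cells, and the share counted depends on power. In simulated genes with a mean of at least 50 normalised reads, the interaction test at 3 h recovered 96% of 2-fold differences. It recovered 30% of the smallest simulated, so shares at different sizes of change are not compared. At 3 h, 377 of 1713 wild-type rises (22.01%) were attenuated in the mutant, and 126 of the 288 that were at least 2-fold (43.8%). Those 288 genes had a median log2 change of 1.40 in wild-type and 0.48 in mutant cells. They were selected on their wild-type change, which favours a larger wild-type median. Of 1250 falls, 59 were attenuated (4.72%). Of the 56 falls of at least 2-fold, 1 was exaggerated and 55 had no interaction call, with medians of -1.22 and -0.73. At 24 h, 2125 of 4917 rises (43.2%) and 2499 of 5030 falls (49.7%) were attenuated, including 706 of 1130 rises (62.5%) and 311 of 599 falls (51.9%) of at least 2-fold. The attenuated genes numbered 436 at 3 h and 4624 at 24 h. By its definition the count does not separate weaker responses from reversed ones. Of wild-type changes of at least 2-fold, 14 of 288 rises and 0 of 56 falls at 3 h were called opposite in the mutant. At 24 h these were 82 of 1130 rises and 25 of 599 falls. An exaggerated response, called with the same sign as the wild-type change, was seen for 30 of the rises at 3 h and 574 at 24 h. It was also seen for 8 of the falls at 3 h and 355 at 24 h. Many genes were also called in the same direction in both genotypes: 842 rises at 3 h and 2759 at 24 h, where independent lists of these sizes would share 163 and 1441, and 594 and 2736 falls, against 97.8 and 1403.

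**Figure D3:**
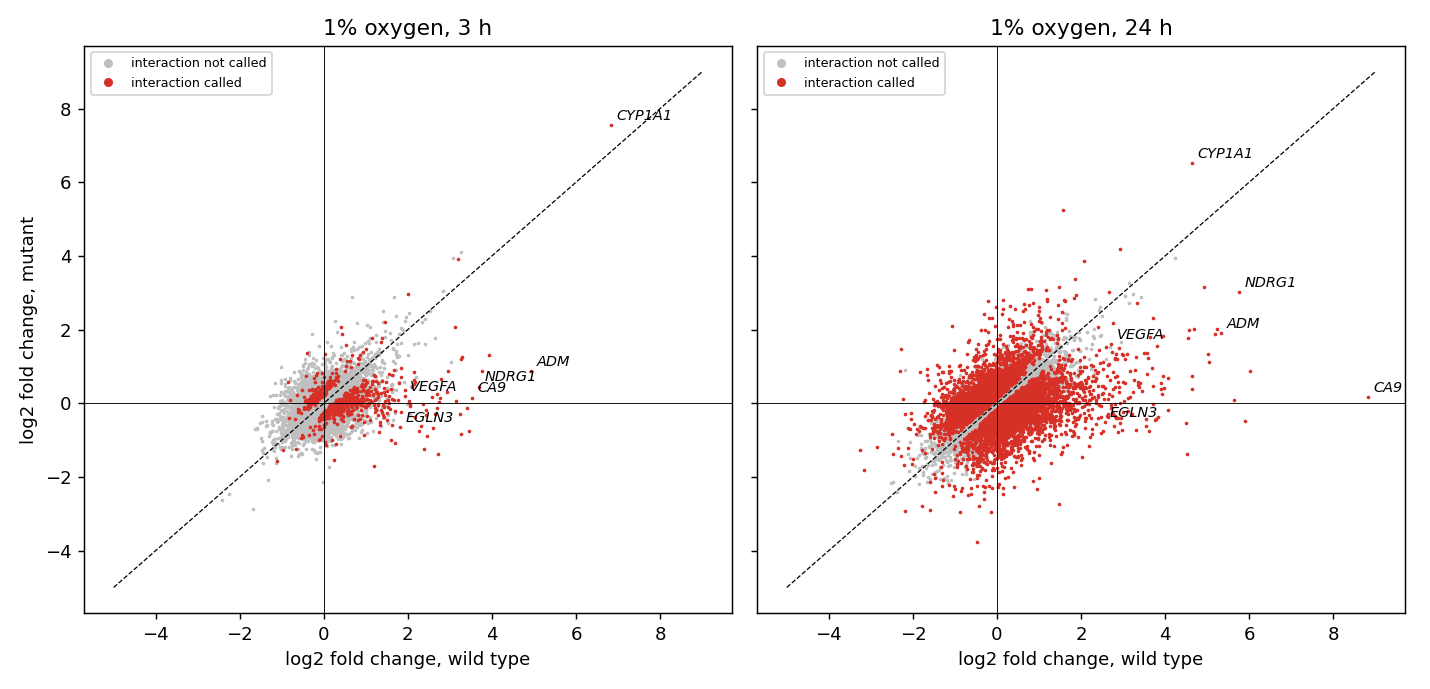
Log2 fold change after 3 h (left) and 24 h (right) of hypoxia in wild-type (horizontal) and mutant cells (vertical), with a point for each gene, genes with a called interaction in red and a dashed line of equal change. NDRG1 lies below that line, at 5.76 in wild-type and 3.02 in mutant cells at 24 h, and CYP1A1 above it, at 4.65 and 6.52.

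At 21% oxygen the mutant cells already differed from wild-type cells at 6983 genes (42.9%), 3529 higher and 3454 lower. Interferon-stimulated genes were higher: IFIT1 (ENSG00000185745, chromosome 10, 91152303 to 91166244), which encodes an antiviral RNA-binding protein, had 42.5 ± 9.52 normalised reads in wild-type and 2143 ± 87.3 in mutant cells (SD, n = 3). The helicase gene DDX60 was higher by 5.89 on the log2 scale, IFI27 by 5.03 and the cadherin gene CDH11 by 5.45. PKP3 (ENSG00000184363, chromosome 11, 392614 to 404908), which encodes a desmosomal plaque protein, fell from 1572 ± 61.1 to 9.34 ± 2.78. The hexokinase gene HK2 was lower, at -2.21 ± 0.087 (SE).

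All 21 interferon-stimulated genes tested were higher in mutant cells (21, adjusted over the list alone), with OAS3 at 2.65 and IFI6 at 4.14 (median 2.65, adjusted p = 2.09e-30, and 0.0108 with an estimated correlation). The glycolysis and other HIF target lists gave adjusted p = 0.131 and 0.981. HIF1A was lower by 0.38 ± 0.045 in the mutant (log2 difference -0.38), and EPAS1 was higher by 0.82 ± 0.079. Mitochondrially encoded genes were lower in 8 of 13 cases (8, adjusted over the list alone), with MT-CO1 at -0.56 (adjusted p = 0.0105, and adjusted p = 0.626 with an estimated correlation). Mutant normoxia replicate 3, at 11.8% of reads, lay within the wild-type range of 10.84% to 11.98%. Ribosome biogenesis genes were lower in 10 of 20 cases and higher in 2 (11 and 2, adjusted over the list alone), with GNL3 at -0.77 (adjusted p = 0.00392, and adjusted p = 0.0993 with an estimated correlation). The luminal list gave adjusted p = 0.430, with MUC1 at -1.18, and the mesenchymal list 0.928, with FN1 at -1.73 and TWIST1 at 2.85. The mesenchymal median was 0.10 and its mean 0.62. Histone genes were lower in 7 of 9 cases (7, adjusted over the list alone, adjusted p = 0.00115, and 0.0215 with an estimated correlation), with H2BC21 at -0.53. Genotype and cell line change together here, so these differences cannot be assigned to the HIF1A mutation alone.

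**Figure D4:**
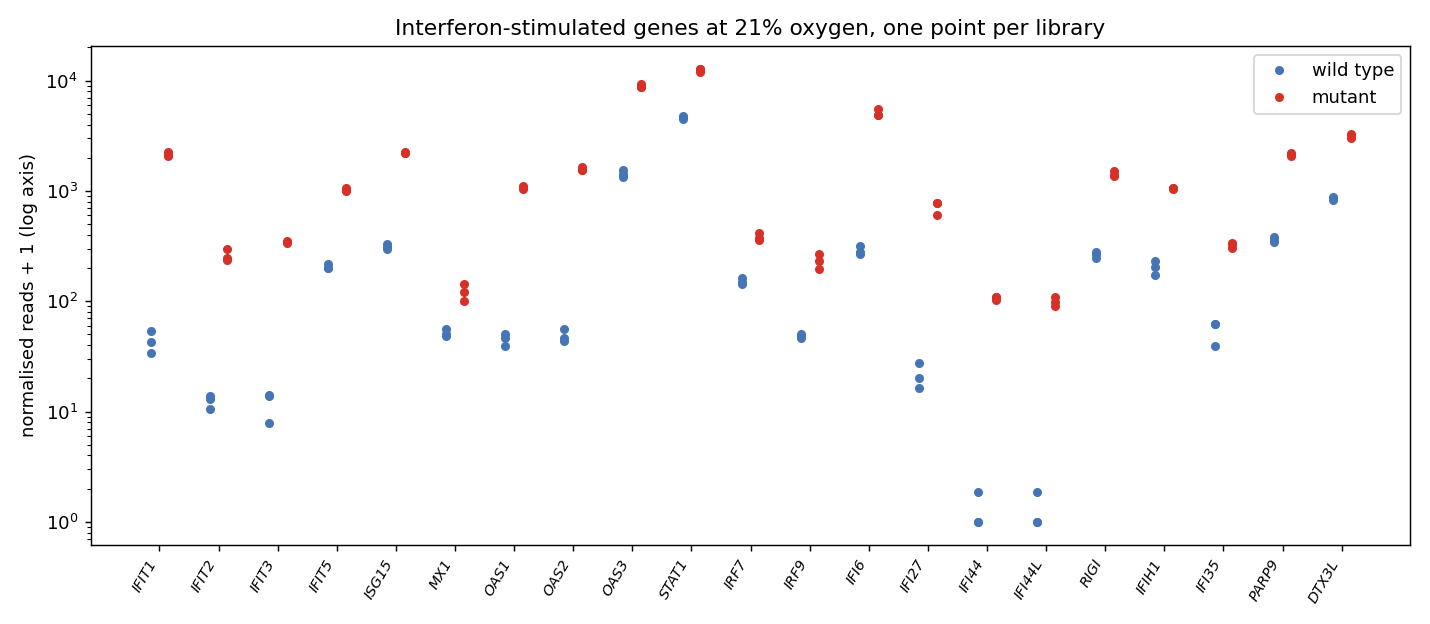
Normalised reads plus 1, on a log axis, of the 21 interferon-stimulated genes in the 3 wild-type and 3 mutant normoxia libraries, with a point for each library. The mutant libraries lie above the wild-type libraries for all 21 genes, with STAT1 averaging 4655 in wild-type and 12450 in mutant cells.

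Under hypoxia the genotypes differed in both sets of genes. At 3 h, 7742 genes were called, 3825 higher and 3917 lower in the mutant, and at 24 h 10458, 5518 higher and 4940 lower. The higher share at 24 h was 52.8%, against 41.7% with upper-quartile scaling. HK2 was lower in mutant cells by -4.89 ± 0.087 at 3 h (log2 difference, SE, n = 3 per group), and PFKFB4 by -4.14. At 24 h, PGM1, which links glycogen to glycolysis, was at -5.35 ± 0.131, PGK1 at -3.55 and the glycogen branching gene GBE1 at -3.91. IFIT1 was higher by 5.56 at 3 h and 6.81 at 24 h, and PKP3 was at -8.32 and -8.15. HIF1A was at -0.31 at 3 h and 0.49 at 24 h.

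Interferon-stimulated genes were higher in all 21 cases at both times (21, adjusted over the list alone), with adjusted p = 6.69e-26 and 4.78e-18, and 0.0168 and 0.0405 with an estimated correlation. Glycolysis genes were lower in 19 of 23 cases and higher in 2 at 3 h (20 and 2, adjusted over the list alone, adjusted p = 1.51e-16), and lower in 22 cases at 24 h (22, adjusted over the list alone, adjusted p = 3.78e-22). Other HIF targets were lower in 32 of 35 cases and higher in 2 at each time, also when adjusted over the list alone, with medians of -1.54 and -2.11 (adjusted p = 3.66e-27 and 7.12e-22). At 3 h nuclear RNAs were higher in 6 of 7 cases (6, adjusted over the list alone, adjusted p = 0.0311, and adjusted p = 0.289 with an estimated correlation), a call also lost with the stricter filter. Histone genes were lower in 7 of 9 cases at 24 h (7, adjusted over the list alone, adjusted p = 6.21e-05, and 0.00685 with an estimated correlation), with H4C8 at -2.01. Whether higher or lower calls were in the majority changed under at least 1 other scaling in 10 of the 11 comparisons. The exception was the interaction at 3 h (26.5% higher, and 32.1% with library size only). Besides the shares given above, the higher share went from 49.4% to 51.4% with upper-quartile scaling in wild-type cells at 24 h, from 49.2% to 55.5% for 24 h against 3 h in wild-type cells, and from 50.5% to 47.9% for mutant against wild type in normoxia. For mutant against wild type at 3 h it went from 49.4% to 54.8% with library size only. Of the 264 list tests in the 11 comparisons, 125 passed at the preset correlation and 52 with an estimated correlation.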

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

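The tests of explanations for 3 patterns below (interferon-stimulated genes, aryl hydrocarbon receptor targets and residual HIF targets in mutant cells), and the counts over other splits of the libraries, were chosen after the results were seen.

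The hypoxia responses differed between genotypes by an interaction test at 630 genes at 3 h and 7319 at 24 h, and 436 and 4624 wild-type responses were attenuated. A fit with additive terms for genotype and oxygen was made for each gene. What it left over was exchanged between genotypes within oxygen conditions in 100 draws, the real arrangement included. The highest count in the other draws was 147 and 2807 for the interactions and 90 and 1662 for the attenuated responses. The real arrangement gave the largest count each time (1 of 100 draws each). A real interaction stays in what is left over, and mixing it widens the spread in the other draws. The draws therefore cannot decide whether chance gave these 4 counts. At 3 h the interaction also passed, at both correlations, for the lists of glycolysis (median difference -0.55), oxygen sensing (-0.07), other HIF targets (-1.45), collagen modification (-0.59), histones (0.15) and nuclear RNAs (0.44). At 24 h it passed for glycolysis (-1.76), other HIF targets (-2.13), collagen modification (-1.23), chromatin dioxygenases (-0.34), ribosome biogenesis (0.70) and histones (-0.50). Both FOS (-3.60) and PPP1R3C (-2.91) moved in opposite directions in the genotypes at 3 h, and CCN2 (3.16) and PPARGC1B (2.46) at 24 h, by the same test.

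In the 9 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split gave 2963 genes in wild-type cells at 3 h, where the highest other split gave 1. In the other 8 comparisons the real counts were 9947 for wild-type cells at 24 h, 2823 and 9306 for mutant cells at 3 h and 24 h, 6983, 7742 and 10458 for mutant against wild type, and 9079 and 8347 for 24 h against 3 h. Their highest other split gave 0 with limma. Every other split mixes libraries of both groups, so a real difference enters the spread and lowers the count. The low counts are therefore no measure of what chance would give.

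Interferon-stimulated genes were higher in mutant than in wild-type cells at normoxia. Scaling between libraries is argued against, since the lowest list median over the scalings was 2.64, and so is 1 mislabelled or mixed library, since 21 of 21 genes had all 9 mutant libraries above all 9 wild-type libraries. A difference between the cell lines apart from HIF1A cannot be told apart from the mutation: 21 genes were higher in all 3 oxygen conditions, but the labels give 1 mutant line and no rescue. An effect of HIF1A loss stays open as an untested biological explanation.

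Aryl hydrocarbon receptor targets rose after 3 h of hypoxia in both genotypes, a list of 9 genes chosen after CYP1A1 was seen (medians 1.88 and 2.00, with 7 and 8 genes higher). Scaling between libraries is argued against by a lowest median of 1.85. The mutant to wild-type ratio of medians was 1.06, so the median rise was not smaller in mutant cells. Whether these cells keep some HIF1A activity is not known, so a need for HIF1A activity is not decided. Handling or medium at the switch to hypoxia cannot be told apart from low oxygen. The wild-type median was -1.12 at 24 h against 3 h, and the labels name no normoxia group handled and timed alongside. That limit holds for every comparison of hypoxia with normoxia, not only for these targets. A response to low oxygen that does not need HIF1A may account for the rise, as a hypothesis.

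Some HIF targets were still higher at 24 h in the mutant: 30 of 49 glycolysis and other HIF targets that had at least doubled in wild-type cells. Of all 1130 genes that had risen at least 2-fold in wild-type cells, 569 were called higher in the mutant. The 30 rises ran from 0.15 for FAM162A to 3.02 for NDRG1 on the log2 scale. Wild-type cells among the mutant cells are argued against. The 3 CA9 reads at 24 h allow a share of up to 0.193% (95% interval), yet 30 genes rose by more than that share gives. The shares implied by single genes ran from -22.1% to 103%, with a median of 3.89%. A reduced HIF1A activity acting alike on all targets, as the only influence on them, is argued against by the 11 genes that fell. They were among the 19 not called higher, of which the other 8 were not called either way. A partial HIF1A activity beside other influences on these genes was not tested and stays open. EPAS1 activity cannot be decided, since EPAS1 rose by 0.88 in the mutant at 24 h and fell by 0.30 at 3 h (adjusted p = 0.00662, and 0.0581 without mutant normoxia replicate 3), when NDRG1, KDM3A, ADM and DDIT4 were already higher, and no group lacks EPAS1. It is a candidate explanation that these data leave open.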

How the results depend on the processing

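The alternatives with TMM scaling, edgeR, pseudocounts of 0.5 and 8 and the list tests without each library were chosen after the data were seen. In 272 of 284 alternatives the 14 counts stayed within 1.5 times their main value, and no list test or named gene was called with the opposite sign. Whether higher or lower calls were in the majority did change with scaling, in 10 of the 11 comparisons. Of the 12 exceptions, 11 follow from the stricter definition of a call. With a minimum change of 2-fold the counts were 344 and 1729 genes in wild-type cells at 3 h and 24 h, 225 and 1397 in mutant cells, 121 and 1383 for the interactions, 964, 1179 and 2247 for mutant against wild type at normoxia, 3 h and 24 h, and 1180 and 928 for 24 h against 3 h. The other exception was the estimated correlation, with which 52 list tests passed, against 125. Single list tests kept their call in 1158 of 1250 alternatives and 92 were weaker, 73 of them with the estimated correlation. Named genes kept their call in 16576 of 16942, with 281 weaker and 85 stronger. The cause was not tested for lists or genes.

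Leaving out each library gave 2381 to 2489 genes in wild-type cells at 3 h, 9342 to 9469 at 24 h, 2089 to 2792 and 8520 to 8914 in mutant cells, 509 to 720 and 6818 to 7238 for the interactions, 6214 to 6555, 6955 to 7252 and 9735 to 9906 for mutant against wild type, and 8378 to 8478 and 7583 to 7872 for 24 h against 3 h. Attenuated responses numbered 360 to 447 and 4256 to 4585, and list tests passed 123 to 131 times.

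On the recovered reads edgeR tested 16306 genes and called 3013, 9872, 2973, 9434, 616, 7240, 6976, 7944, 10465, 8971 and 8640 in the order of comparisons above, and shared 95.1% to 99.1% of the limma calls, all with the same sign. DESeq2 shared 92.2% to 96.0%. Over all genes tested, the replicate numbers showed no pairing of the libraries. The deviations of 45 same-number pairs correlated between -0.139 and 0.067, and 8 of 18 libraries matched their own number best. Some interferon-stimulated genes did share an order. At 3 h, OAS1 had 34.2, 54.6 and 43.5 normalised reads in wild-type replicates 1 to 3, and 781, 1029 and 864 in mutant ones. OAS2, MX1, RIGI and IFIH1 had that order in both genotypes, and IFIT1 did not. A replicate effect on such genes was not tested. With the replicate block the counts were 2869, 9913, 2740, 9233, 613, 7227, 6854, 7627, 10404, 9007 and 8297, the attenuated responses 424 and 4581, and the list tests 124. Depth limits genes such as CA9, whose 3 reads in wild-type normoxia leave its ratio at 3 h between 10.4 and 155.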

Other observations

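The test of whether aryl hydrocarbon receptor targets differ between genotypes was chosen after the values were seen. The fixed lists held only NQO1 of the 9 tested targets. At 3 h, 7 of the 9 were higher in wild-type and 8 in mutant cells. CYP1B1, which metabolises oestrogens and polycyclic hydrocarbons, went from 4803 ± 135 to 43880 ± 2090 and 14500 ± 221 normalised reads at 3 h and 24 h in wild-type cells (SD, n = 3), and from 2082 ± 28.2 to 31290 ± 3310 and 14500 ± 1440 in mutant cells. AHRR, which encodes a repressor of the receptor, went from 316 ± 42.8 to 1162 ± 65.8 and 363 ± 41.1 in wild-type cells, and in mutant cells from 255 ± 38.4 to 1015 ± 49.3 and 498 ± 9.61. At 24 h all 9 were higher than in normoxia in mutant cells (median 1.37), while in wild-type cells 4 were higher and 1 lower (median 0.54). The response was larger in the mutant for 4 of 9 at 3 h and 7 of 9 at 24 h, by the interaction test. It started from a lower level, since 7 of the 9 were lower in mutant than in wild-type cells in normoxia (median -0.31). Compared under hypoxia, 3 were higher and 3 lower in the mutant at 3 h (median -0.08). At 24 h 6 were higher and 0 lower (median 0.46).

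The reads on mitochondrially encoded genes made up 11.98%, 11.97% and 10.84% of each wild-type normoxia library, 10.94%, 10.09% and 9.83% at 3 h, and 8.96%, 8.53% and 8.74% at 24 h. In mutant cells the shares were 9.62%, 9.68% and 11.8% in normoxia, 8.21%, 10.13% and 8.60% at 3 h, and 9.38%, 8.68% and 7.73% at 24 h.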
